A study of Mus musculus with 4 samples.

How the data were processed

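Total RNA from brainstem/cerebellum and spinal cord of transgenic and wild-type mice aged 24 weeks was extracted with TRIzol, cleaned on columns, amplified and labelled with Cy3 by a low-input kit, per the labels' protocols. Each sample was hybridised to 1 Agilent array in 1 colour. The mice had a background of 3 strains, per the labels. Groups were taken from the sample titles and their genotype and tissue labels, with 1 array in each of the 4 groups. The labels do not say whether a sample is 1 animal or a pool, nor whether both tissues of a genotype came from the same animals.

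The deposited scanner files hold spot intensities on a linear scale, made with Agilent Feature Extraction. The submitters' processing notes give version 9.5.1.1 of that software, while the version per the file headers is 10.7.1.1. Per the file headers, the processed intensity of each spot was background-subtracted and detrended within the array, low values were replaced by a surrogate, and nothing was scaled between arrays. Probe coordinates refer to the mouse build mm9, per the file headers. The authors' processed values in the series table are intensities as well, on a linear scale. Their normalization is not given in the sources used here. All 4 columns had the same median of 30.4, and the values followed a quantile normalization of the processed signals computed here with a Pearson correlation of 0.99999, so scale, centring and direction could be read from the values. They served as an alternative.

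The main values were log2 of the processed signal minus the 75th percentile of each array, with control spots and outlier-flagged spots left out. The 75th percentile was at a signal of 463 and 445 on the transgenic and wild-type brainstem/cerebellum arrays and 414 and 686 on the transgenic and wild-type spinal cord arrays. Outlier flags removed 83, 134, 83 and 63 spots in this order. Spots of 1 probe were averaged. Of 56605 probes, 45603 were named through a gene table of assembly GRCm38.p6 or by symbol: 32989 by accession, 10151 by a symbol in the table, 497 by a synonym, and 1966 kept the symbol of the file alone. The other 11002 were unnamed and were counted apart. The coordinates of that table were not used, since the builds differ. Where a gene had several probes (11418 genes), the probe with the highest mean over the 4 arrays stood for it, and probes that disagree are named beside the value.

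A gene entered a count over all genes when its probe was well above background on both arrays compared, and the threshold was 2-fold. Counts of gene list members also include members above background on 1 array only whose bound, defined next, passed 2-fold. For a gene above background on 1 array only, the difference is a bound: the brighter value minus the higher of the dim probe's own value and the lowest signal among probes well above background on the dim array. A count of shared genes is set beside the number that independent sets would share, the product of both counts divided by the number of genes. For a gene list, the median difference over members above background on at least 1 of the arrays was placed among 10000 random lists of the same size, matched on mean signal in 20 bins, as a description of these arrays. The technical error came from 300 probes with 10 spots each and from the spike-in control probes, pooled over arrays in bins of signal.

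The following choices were made before the data were examined. There were 41 gene lists with 536 entries, covering glial states, immune pathways, lipid synthesis, stress responses, neuron types, regions, neighbouring tissues, the cell cycle and sex-linked genes, and 4 entries had no probe. Named genes followed a fixed rule: the 10 largest differences each way in each tissue among genes above background on both arrays and above the median on at least 1; the 10 largest each way in both tissues; up to 4 members per list with the largest difference; the 5 largest bounds each way; the 5 largest differences of differences each way; and the 8 largest tissue differences each way. Some further list members are named as examples beside the count of their list, chosen after their values were seen. Some genes and 1 list that these rules name are not reported here. The alternatives fixed in advance were scaling on the median, quantile normalization, cyclic loess, normexp with an offset of 50 followed by quantile normalization, 3 other filters on dim probes, the mean of probes per gene, the authors' values, thresholds of 1.5-fold and 3-fold and the mean of a list. Scaling on the spike-in control probes and leaving out genes bright on the wild-type spinal cord array alone were added after seeing the data.

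The slide was read from the files. It holds 3 arrays in one case and 1 in the other, so a block for the slide cannot be fitted in a comparison of 2 arrays. Data were simulated with the technical error above for the brainstem/cerebellum comparison over 16716 genes. Of genes changed by 1.5 or 2.5 on the log2 scale 100% were called, and 54.0% of those changed by 1. None of those changed by 0.5 and 0.163% of unchanged genes were called. The simulation holds spot noise alone, with a median SD of a difference of 0.12. The robust SD of the measured differences over genes was 0.23 in brainstem/cerebellum and 0.57 in spinal cord. The 0.163% is therefore not a rate of false calls for the real arrays. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and limma 3.58.1 in R 4.3.3 for cyclic loess and normexp.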

Results

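Gene expression was measured in brainstem/cerebellum and in spinal cord of transgenic mice, described by the submitters as MSA Tg mice (multiple system atrophy is a neurodegenerative disease with protein deposits in oligodendrocytes), and of wild-type mice at an age of 24 weeks. Each of the 4 combinations of genotype and tissue was hybridised to 1 array in 1 colour, so no difference has a replicate check, no test between groups was run and no p-value is given. The values describe these 4 arrays. Of 59305 spots per array that were not controls, 61.7% on the transgenic and 59.2% on the wild-type brainstem/cerebellum array were well above background. The same share was 60.9% on the transgenic and 64% on the wild-type spinal cord array, and no spot was saturated. The number of arrays, 1 per group, limits the precision. Repeated spots of 1 probe within an array give a technical error: the SD of a difference between 2 spots was 0.09 on the log2 scale for bright probes and 0.66 for the dimmest ones. This error leaves out every difference between animals and between hybridisations. Differences below are log2 values, transgenic minus wild type, unless stated otherwise.

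The wild-type spinal cord array lies on another slide than the other 3 arrays. The comparison of genotypes in brainstem/cerebellum and that of tissues in the transgenic mice each lie within 1 slide. In the spinal cord, slide and genotype cannot be told apart. Across 30420 probes above background on all arrays, the Pearson correlation (over probes, which are not independent replicates) was 0.990 between the brainstem/cerebellum arrays and 0.960 between the spinal cord arrays. It was 0.962 between the transgenic arrays of both tissues. Across slides, the wild-type spinal cord array had 0.968 with the wild-type and 0.965 with the transgenic brainstem/cerebellum array. The lowest value, 0.945, was that of transgenic spinal cord with wild-type brainstem/cerebellum, which share a slide.

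The first comparison asks how the brainstem/cerebellum of the transgenic mice differs from that of wild-type mice. Genes of innate immunity, antigen presentation and astrocyte reaction were higher on the transgenic array, and few genes were lower. Among genes above background on both arrays, the largest difference belonged to Lcn2, a secreted siderophore-binding protein of reactive glia, at 5.78, or 54.8-fold (chromosome 2, 32240199 to 32240258 in mm9, the build of the probe coordinates). The class II genes H2-Aa, H2-Ab1 and H2-Eb1, whose products present peptides to T cells, followed at 5.69, 4.69 and 4.60, with Cd74, their invariant chain, at 4.43. Arg1 (5.38), Scgb3a1 (5.18), the metalloprotease inhibitor Timp1 (4.81), Acp5 (4.09) and the monocyte chemokine Ccl2 (4.04) complete the 10 largest. Genes seen above background on the transgenic array alone can be given only a bound. The largest bounds were at least 73.3-fold for Ccl8, 63.8-fold for Retnla, 32.6-fold for Rnase2a, 31.1-fold for Saa3 and 17.4-fold for Ccn5.

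Among 16716 named genes above background on both brainstem/cerebellum arrays, 452 were at least 2-fold higher and 49 at least 2-fold lower on the transgenic array. A further 200 higher and 59 lower genes passed 2-fold as a bound. The central 95% of genes lay between -0.56 and 1.04. With quantile normalization 83 genes were lower, and with normexp background correction 187 were higher and 14 lower.

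Of 20 measured genes of disease-associated microglia, the state of microglia around lesions, 11 were at least 2-fold higher and none lower in brainstem/cerebellum. Their median was 1.33, with Cst7 at 3.15, Lgals3 at 3.04, Clec7a at 2.62 and Gpnmb at 2.41. Igf1 of this list stood at 2.49 at its brightest probe and at -0.13 at another. Of 23 reactive astrocyte genes 19 were higher, with a median of 1.44 and with Serpina3n at 3.67, Cxcl10 at 3.40 and the intermediate filament gene Gfap at 1.44. Complement genes had 9 of 11 members higher and a median of 2.0, including C3ar1 at 2.71, C4b at 2.27 and C1qa at 2.0. Interferon response genes had 11 of 16 higher and a median of 1.43, with Oas1a at 1.95 and Ifi27l2a at 1.89. Antigen presentation genes had 10 of 16 higher and a median of 1.11, and the class I gene H2-K1 stood at 1.0. Of 14 cytokine and chemokine genes 10 were higher, with a median of 2.78, or 1.66 when members below background on 1 array are set to their bound. Ccl7 was at 3.06, Ccl5 at 3.06 and Ccl12 at 2.86. The medians of these 6 lists lay above those of all 10000 random lists of the same size and signal. Homeostatic microglia genes had a smaller median of 0.62 and 1 of 12 members at least 2-fold higher, Fcrls at 1.47. Of 10 proliferation genes 4 were higher, with Mki67 at least 8.88-fold, and their median was 1.07, or 0.96 at the bounds.

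Cholesterol synthesis genes and several neuron lists had medians below 0 in brainstem/cerebellum, with few members past 2-fold, while the Purkinje cell list did not. The 18 cholesterol synthesis genes had a median of -0.42, below all random lists, and none was 2-fold lower. Sc5d was at -0.79, Nsdhl at -0.65 (0.44 at its other probe) and Dhcr7 at -0.57. Cholinergic and motor neuron genes had a median of -0.45 and 1 of 9 members lower, Chodl at -1.55. The acetylcholine-synthesising enzyme gene Chat stood at 0.03. Monoaminergic neuron genes had a median of -0.23 and 2 of 10 lower, the serotonin transporter gene Slc6a4 at -1.35 and Tph2, which makes serotonin in the brain, at -1.01. Pan-neuronal genes had a median of -0.21 and transmitter genes of -0.29, each with no member past 2-fold. Myelin and mature oligodendrocyte genes had a median of 0.06 with none of 20 past 2-fold, and precursor genes of 0.09 with none of 13. Among the lowest single genes were also the vascular receptor gene Kdr at -1.30, the arterial gene Gkn3 at -1.54, the GABA transporter gene Slc6a11 at -1.05 and Gata3 at -1.16. Cystm1, the lowest at -3.08, and Rian at -1.40 disagreed with their other probes, which gave -0.13 and -0.07. Pisd-ps3 (-1.06) and 4930506C21Rik (-1.08) complete the 10 lowest among genes above the median signal on at least 1 of both arrays. The largest lower bounds, on genes above background on the wild-type array alone, were at least 6.86-fold for the receptor gene Olfr1208 and a bounded difference of -2.43 for Mst1.

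**Figure D1:**
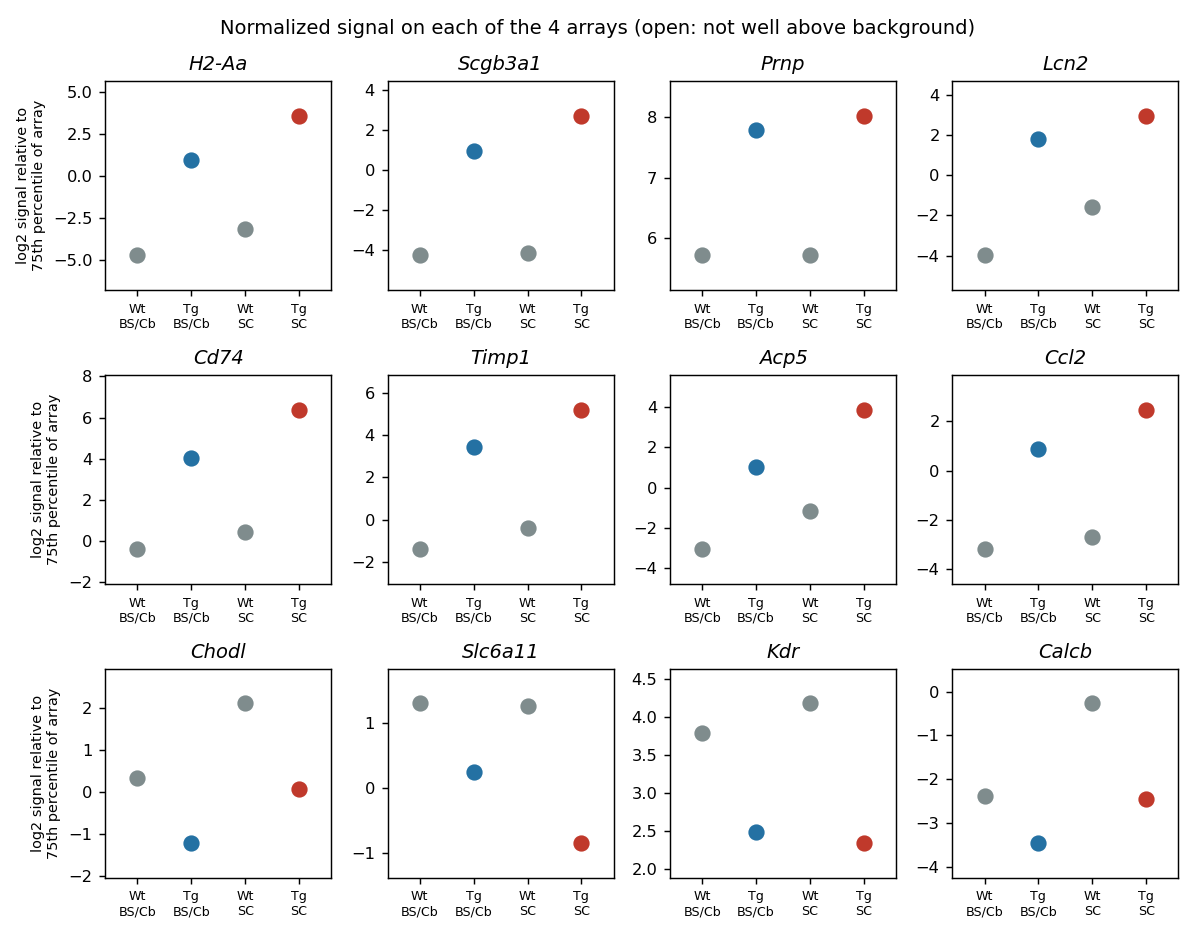
Normalized signal (log2, relative to the 75th percentile of each array) of 12 genes on the 4 arrays, 1 point per array, wild type (Wt) in grey and transgenic (Tg) in colour, for brainstem/cerebellum (BS/Cb) and spinal cord (SC), with a scale of its own for each gene. Cd74 lies at -0.40 in wild-type and 4.04 in transgenic brainstem/cerebellum and at 0.45 and 6.38 in spinal cord. Prnp was chosen after its values were seen.

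The second comparison asks the same of the spinal cord. Genes of the same immune and glial lists were higher on the transgenic array. At the main scaling, the median was larger than in brainstem/cerebellum for all of these lists but the interferon response. Spike-in scaling moved the median of all genes from -0.05 to -0.40 here and from -0.06 to -0.01 in brainstem/cerebellum. Together these shifts are at least as large as the gap for lists with close medians. An example is complement (2.0 and 2.40), whose order rests on the scaling. The cytokine and chemokine medians (2.78 and 2.86) cover 14 and 15 members and were 1.66 and 2.86 at the bounds. Gene by gene, the spinal cord difference of that list exceeded the brainstem/cerebellum one by a median of 0.68, more than these shifts together. Members below background entered that excess with no bound. Among genes above background on both arrays, Scgb3a1 (6.84), the ribonuclease gene Rnase2a (6.75), H2-Aa (6.71), the chemokine gene Ccl8 (6.67) and Gdf15, a stress-induced cytokine, (6.36) led. Retnla (6.28), the serotonin receptor gene Htr2b (6.18), Saa3 (6.18), the macrophage gene Ms4a7 (6.12) and Cd74 (5.93) followed. Arg1, which encodes arginase 1, was at least 243-fold higher. Apoc4, Clca3a2, Ear12 and the proton pump subunit gene Atp6v0d2 were at least 79.0-fold, 79.0-fold, 78.9-fold and 61.1-fold higher.

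Of 17001 named genes above background on both spinal cord arrays, 1440 were at least 2-fold higher and 1081 at least 2-fold lower on the transgenic array, with 360 and 185 more as bounds. The central 95% of genes lay between -1.40 and 2.07, a wider range than in brainstem/cerebellum. The spike-in control probes, RNA added at labelling, were 0.42 higher in median on the transgenic array, with a range from -0.17 to 0.66 over 7 probes. Scaled on these probes, an alternative chosen after seeing the data, the median of all genes moved to -0.40, with 902 genes higher and 2605 lower. That is 25.7% of calls higher against 57.1%, so directions of small differences here hold relative to the 75th percentile of each array.

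Disease-associated microglia genes had 19 of 20 members at least 2-fold higher in spinal cord and a median of 2.70. Gpnmb stood at 5.32, Cst7 at 4.49, Clec7a at 4.33, Itgax at 3.88 and the lipid receptor gene Trem2 at 2.91. Homeostatic microglia genes moved apart: 6 of 12 were higher and 2 lower, with a median of 0.97, Fcrls at 2.74, Cx3cr1 at 1.86, Siglech at -1.61 and Olfml3 at -1.73. The other Olfml3 probes gave -0.11 to 1.68. Reactive astrocyte genes had 18 of 22 higher and a median of 2.06, with Timp1 at 5.58, Serpina3n at 4.66, Lcn2 at 4.53 and Gfap at 1.08. General astrocyte genes had a median of -0.59 with 3 of 12 lower and 1 higher, Fgfr3 at -1.14, Gjb6 at -1.19 and Sox9 at 1.08. Gja1, the third of the lower ones, stood at -1.81, while its other probes gave -0.43 to -0.41. In brainstem/cerebellum that list had a median of 0.03, which turned to -0.01 with the median scaling.

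Antigen presentation genes had 14 of 16 higher in spinal cord and a median of 1.90, complement 9 of 11 and 2.40, interferon response 12 of 16 and 1.12, and cytokines and chemokines 13 of 15 and 2.86. C3ar1 stood at 4.13, C1qa at 3.40, Ifi44 at 2.93, Ccl2 at 5.17 and Ccl7 at 4.31, and Il6 was bounded at 4.28. Tnf was at -0.74. Proliferation genes had 9 of 10 higher and a median of 2.92, or 2.56 at the bounds, with Top2a at 4.08, Ccnb1 at 3.72 and Mki67 at 3.0. Immediate early genes had 8 of 14 higher and 1 lower, with a median of 1.28, Ccn1 at 3.47, Junb at 2.29 and the synaptic gene Arc at -1.32. Oligodendrocyte precursor genes had 4 of 13 higher and a median of 0.75, with Cspg4 at 2.36 (0.35 at its other probe), Gpr17 at 1.45 and Pdgfra at 1.08 (0.07 at its other probe). Mature myelin genes had a median of 0.24, which was -0.12 with spike-in scaling, and 1 of 20 members past 2-fold, Cldn11 at 1.21. Lysosomal and autophagy genes had 7 of 18 higher, with Ctsd at 2.05, Ctsl at 1.92 and Hexa at 1.69. Their median was 0.28 and turned to -0.07 with spike-in scaling.

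Cholesterol synthesis genes had 7 of 18 members at least 2-fold lower in spinal cord and none higher, with a median of -0.77 below all random lists. Nsdhl stood at -1.41, Srebf2, the transcription factor of this pathway, at -1.40 and Fdft1 at -1.38. The other Srebf2 probe gave -0.01. Cholinergic and motor neuron genes had 3 of 10 lower and a median of -0.98, or -0.95 at the bounds, with Chodl at -2.04, Calca at -1.45, Ache at -1.18 and Chat at -0.12. The other Chodl probe gave 0.25. Pan-neuronal genes had 3 of 15 lower, the neurofilament genes Nefh at -1.41, Nefm at -1.35 and Nefl at -1.15, and a median of -0.58. Transmitter genes had 2 of 11 lower and a median of -0.67, or -0.64 at the bounds, with Slc6a5 at -1.43. Oxidative phosphorylation genes had 2 of 16 lower and a median of -0.62, with Cox6c at -1.12. The skeletal muscle list, which stands for tissue around the cord, had 4 of 11 lower and a median of -0.89, and the choroid plexus list 3 of 7 and -0.86. Peripheral myelin genes had 2 of 9 lower, among them Prx at -1.74, while the median of 0.28 and the mean of -0.15 differ in sign, and the median was -0.07 with spike-in scaling.

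The 10 genes furthest below 0 in spinal cord were not among the fixed lists. Vmn1r65 (-6.14), 4930449E01Rik (-6.04), Sprr2g (-5.40), Gm27246 (-5.23), Gm32344 (-4.91), Vgll1 (-4.53), Fam227b (-4.15), Tll1 (-4.14), Trim63 (-4.14) and Olfr1466 (-4.09) made up this group. The other probe of Tll1 gave -0.58. On the wild-type spinal cord array 124 named genes were at least 4-fold above each of the other 3 arrays, compared with 411 on the transgenic spinal cord array, 113 on the transgenic and 50 on the wild-type brainstem/cerebellum array.

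The fixed lists of stress, hormone and metabolic genes were compared as well. In brainstem/cerebellum, immediate early genes had a median of 0.49 with 2 of 14 higher, and glucocorticoid response genes 0.45 with 4 of 12 higher, among them Lcn2 at 5.78 and Plin4 at 1.81. Both medians lay above those of all random lists. The glucocorticoid median was 0.62 in spinal cord, with Lcn2 at 4.53, Plin4 at 2.42 and Cdkn1a at 2.20. Heat shock genes had medians of -0.34 in brainstem/cerebellum, below all random lists, and -0.24 in spinal cord, where the mean was 0.06, and Hspb1 stood at 1.61 and 1.39. The unfolded protein response list had medians of -0.16 and 0.19, the latter -0.17 with spike-in scaling. Oxidative stress genes stood at 0.07 and 0.35, the latter -0.00307 with spike-in scaling, and Hmox1 at 1.56 and 3.35. Lysosomal and autophagy genes had a median of 0.01 in brainstem/cerebellum, which was -0.03 with the median scaling. Circadian clock genes had medians of -0.07 and -0.57, and ribosomal protein genes of 0.04 and 0.41 with none past 2-fold. Oxidative phosphorylation genes had a median of -0.14 in brainstem/cerebellum. Neurotrophic factor genes had a median of -0.29 but a mean of 0.16 in brainstem/cerebellum, and a median of 0.45 in spinal cord, where Gdnf stood at 3.22. Monoaminergic genes had a median of -0.60 in spinal cord, or -0.15 at the bounds.

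Regional and neighbouring-tissue lists were compared between genotypes as well. Granule cell genes had medians of 0.00 in brainstem/cerebellum, which turned negative under 7 alternatives, to between -0.01 and -0.13, and -0.51 in spinal cord. Purkinje cell genes stood at 0.06 and -0.42, forebrain genes at -0.06 and -0.18 and endothelial genes at -0.07 and -0.28. The spinal Hox list had a median of 0.60 over 7 members in brainstem/cerebellum, which was -0.07 over genes above background on all 4 arrays, and -0.17 in spinal cord. Choroid plexus genes had a median of -0.15 in brainstem/cerebellum. Ependymal genes stood at -0.18 and 0.43. Meningeal genes stood at 0.22 and -0.18, with a mean of 0.13 in spinal cord. In brainstem/cerebellum the peripheral myelin list had a median of 0.35, and the skeletal muscle list one of 0.13, which was -0.05 with quantile normalization. Blood genes had medians of -0.23 and 0.42. Lymphocyte genes stood at -0.02, which was 0.04 with spike-in scaling, over 3 members and at 0.23, which was -0.12 with spike-in scaling, over 8. Pituitary genes stood at 0.48, or 0.22 at the bounds, and at 0.16, which was -0.20 with spike-in scaling. Among sex-linked genes, Xist, transcribed from the inactive X chromosome, lay at -1.70 and -1.53 on the transgenic and wild-type brainstem/cerebellum arrays and at -1.37 and -1.82 on the spinal cord ones. The Y-linked Kdm5d differed by -0.98 and -2.37 at low signal (-5.05, -4.07, -5.17 and -2.80 on the same arrays), and Ddx3y, Eif2s3y and Uty were not above background on any array.

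**Figure D2:**
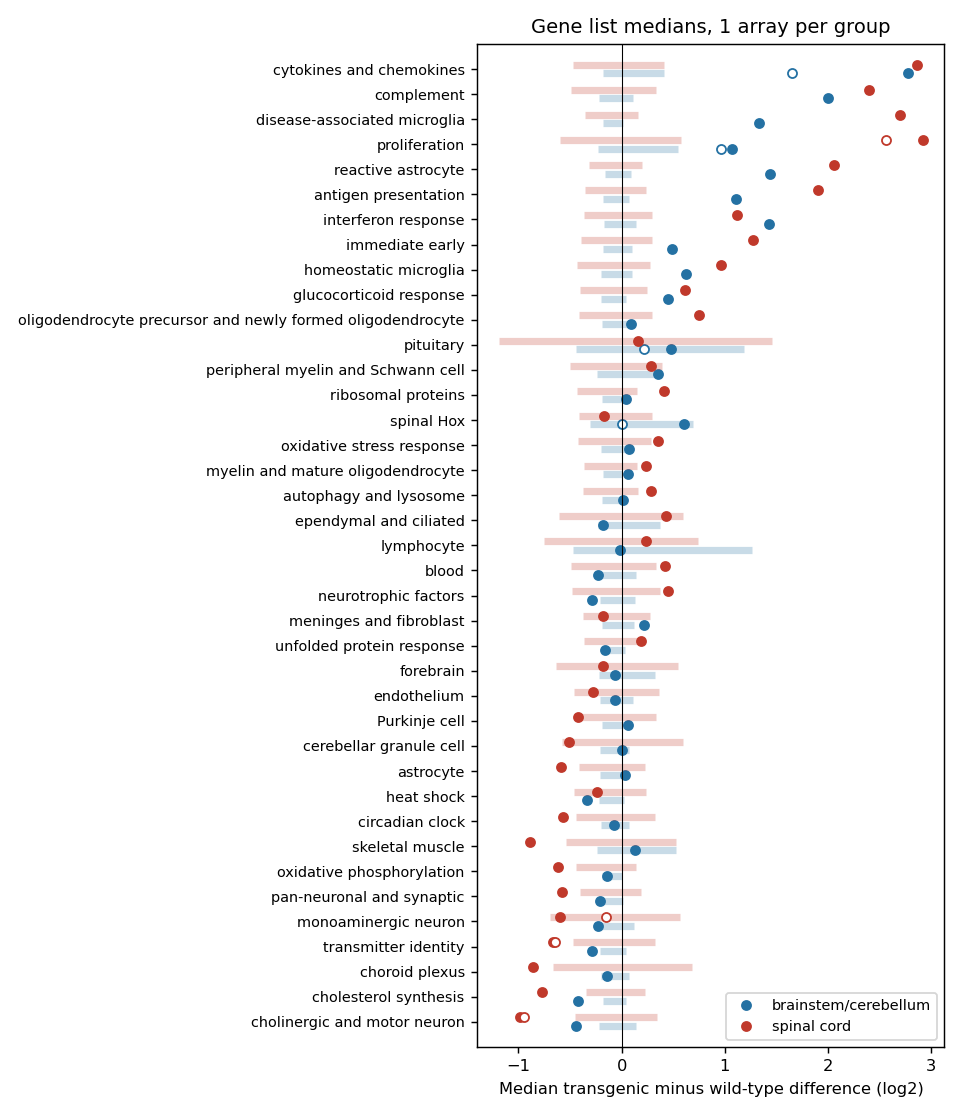
Median transgenic minus wild-type difference (log2, x axis) of the gene lists reported here in brainstem/cerebellum (blue) and spinal cord (red). Filled points are medians of measured differences, open points the median with members below background on 1 array at their bound where this differs, and bars the central 95% of medians of 10000 random lists. The disease-associated microglia list lies at 1.33 and 2.70 and the cholesterol synthesis list at -0.42 and -0.77.

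The third comparison asks which genotype differences the tissues share. H2-Aa, Scgb3a1, Timp1, H2-Ab1, H2-Eb1, Lcn2, Cd74, Acp5, Ccl2 and the Fc receptor gene Fcgr4 had the largest differences common to both among genes above background on all 4 arrays. The smaller of their values in the 2 tissues ran from 5.69 for H2-Aa to 3.98 for Fcgr4, which stood at 5.18 in spinal cord. Of 16270 genes above background on all 4 arrays, 435 were at least 2-fold higher in brainstem/cerebellum and 1229 in spinal cord, and 357 were in both sets, where independent sets would share 32.9. Lower in both were 19 of 40 and 1044, where independent sets would share 2.57. These included the secreted protein gene Wfdc18 (-2.22 and -1.86), Kdr (-1.30 and -1.84), Gkn3 (-1.54 and -1.94), the neuropeptide gene Calcb (-1.08 and -2.19), Slc6a11 (-1.05 and -2.11) and Lhx4 (-1.19 and -1.66). Quantile normalization gave 31 genes lower in both. Another 12 genes were past 2-fold in opposite directions. Across genes, which are not independent replicates, the differences of both tissues had a Pearson correlation of 0.590 and a Spearman correlation of 0.463. No array was part of both differences. An additive fit over both tissues was not used, since the labels do not say whether the tissues of a genotype came from different animals.

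**Figure D3:**
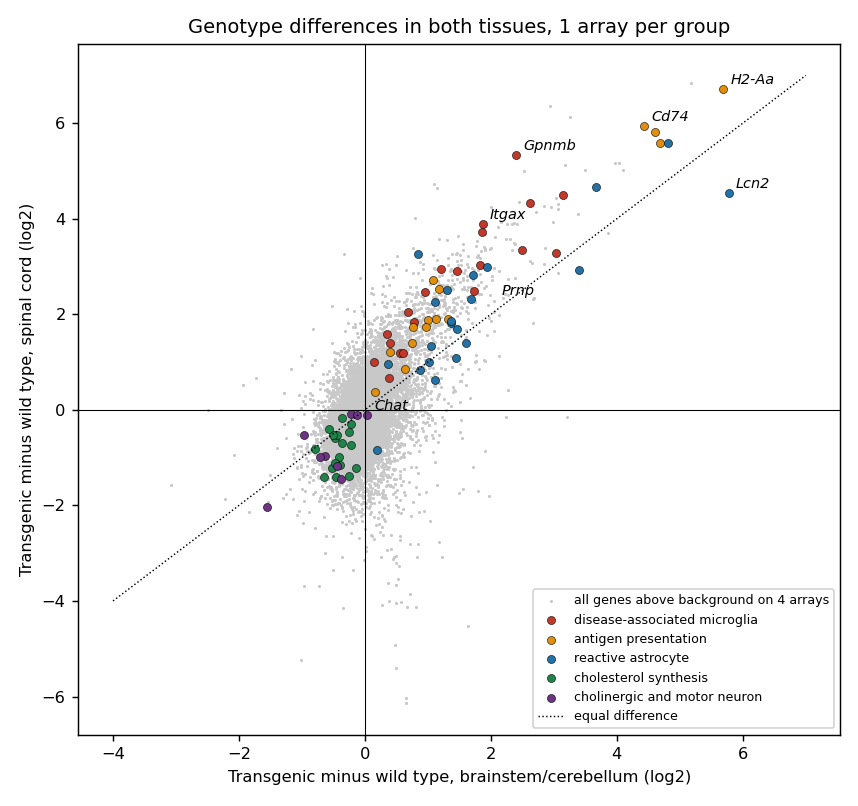
Transgenic minus wild-type difference (log2) in brainstem/cerebellum (x axis) and spinal cord (y axis) for 16270 genes above background on all 4 arrays, with members of 5 gene lists in colour and the line of equal differences dotted. H2-Aa lies at 5.69 and 6.71, and Gpnmb at 2.41 and 5.32 lies above the line.

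Among genes above background on all 4 arrays that also passed the fixed signal filter, the difference between the tissues in their genotype differences was ranked. It was largest for Crym (3.64), Hcst (3.6), the matrix gene Postn (3.50), Gdf15 (3.42) and Rasl11a (3.23). Crym stood at 1.09 in brainstem/cerebellum and at 4.73 in spinal cord, and Postn at 1.15 and 4.64. The other Hcst probes differed from its brightest one in brainstem/cerebellum, with 1.37 to 1.60 against -0.33. Within the same set, Vmn1r65 (-6.79), 4930449E01Rik (-6.69), Vgll1 (-6.16), Sprr2g (-5.89) and Gm32344 (-5.39) had the lowest values, all of them genes bright on the wild-type spinal cord array. By 2-fold, 709 genes had a larger and 864 a smaller difference in spinal cord. With spike-in scaling these were 253 and 2297. Among lists, the proliferation list had a median excess of 1.31 in spinal cord, the disease-associated microglia list of 1.23 and the antigen presentation list of 0.86. The proliferation excess includes members below background on an array, such as Mki67, with no bound set, so its place above the microglia list is not firm. The excess was smaller for the reactive astrocyte list at 0.37. For the complement list at 0.19 and the interferon response list at 0.15 it lay at percentiles 86.0 and 81.2 of random lists. Spike-in scaling lowers every excess by the same amount. With it the median of all genes moved from -0.05 to -0.40 in spinal cord and from -0.06 to -0.01 in brainstem/cerebellum. The reactive astrocyte, complement and interferon response excesses do not exceed this amount, so their sign rests on the scaling. The unfolded protein response list had an excess of 0.61, with the stress transcription factor gene Atf3 at 1.90 and 3.67, and Trib3 at 1.18 and 3.57. None of these differences was tested, and each contains the slide.

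The tissue comparison sets spinal cord against brainstem/cerebellum within each genotype and bears on the tissue labels. All 13 measured Hox genes of the trunk were at least 2-fold higher in spinal cord, with medians of 5.38 in transgenic and 6.95 in wild-type mice, or 4.80 and 5.34 at the bounds. Hoxa7 was at 5.38 and 7.47, Hoxc6 at 4.09 and 4.88, Hoxb7 at 3.87 and 5.34 and Hoxb8 at 3.82 and 4.37. Ranked by the smaller of the values in both genotypes, the noncoding RNA Mira came first at 5.64 and 6.6, and the inflammatory genes S100a9 (6.10 and 4.57) and S100a8 (5.50 and 4.45) and the Schwann cell gene Prx (4.62 and 6.64) were also among the 8 highest. Cerebellar granule cell genes were lower in spinal cord for 11 of 11 members, with medians of -5.24 and -5.93, or -4.06 and -3.94 at the bounds. Purkinje cell genes were lower for 12 of 12, with -2.95 and -2.57. Pcp2 stood at -9.30 and -8.00, Crtam at -7.53 and -7.88, Neurod1 at -6.94 and -6.29, Ppp1r17 at -6.87 and -6.41, Gabrd at -5.24 and -5.93, Car8 at -4.86 and -6.23, En2 at -4.64 and -4.32 and Folr1 at -4.44 and -4.54. Choroid plexus genes had medians of -4.25 and -3.85 and monoaminergic genes of -2.95 and -2.33. Myelin genes were 0.99 and 1.05 higher in median in spinal cord, and skeletal muscle genes 2.08 and 3.32, or 1.80 and 2.90 at the bounds.

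In all, 1692 genes were at least 2-fold higher and 1049 lower in transgenic spinal cord than in transgenic brainstem/cerebellum, and 1118 higher and 709 lower in the wild-type pair. Among the 16270 genes above background on all 4 arrays, 1436 were higher in the transgenic and 1070 in the wild-type pair, with 430 in both sets where independent sets would share 94.4. Lower were 1029 and 642, with 447 in both where independent sets would share 40.6, and the tissue differences of both genotypes had a Pearson correlation across genes of 0.631. Spike-in scaling, chosen after seeing the data, gave 980 higher and 2160 lower genes in the transgenic pair, 31.2% of calls higher against 61.7%, with the median of all genes at -0.37.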

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

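Of the tests of the probes bright on the wild-type spinal cord array, the one on the size of the muscle gene differences was chosen only after the result was seen.

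Named genes past 2-fold in opposite directions in the tissues, and lists with medians of opposite sign that both lay outside the central 95% of random lists and exceeded the technical error, made up 4 results. None of these differences between tissues was tested. The gap junction gene Gja1 stood at 1.97 in brainstem/cerebellum and -1.81 in spinal cord. Its other probes lay between -0.26 and 0.52 in brainstem/cerebellum and between -0.43 and -0.41 in spinal cord. Vgll1 stood at 1.63 and -4.53. The neurotrophic factor list had medians of -0.29 and 0.45, and the blood list of -0.23 and 0.42. The mean of the neurotrophic list was 0.16 in brainstem/cerebellum, so median and mean differ in sign there. Its largest member there was Igf1 at 2.49, which stood at -0.13 at another probe, and 4 members lay above and 6 below 0. In spinal cord Igf1 was also the largest member, with 3.34 at its brightest probe and -0.66 at another. The spinal cord median of the list therefore depends on the probe chosen for Igf1. Spike-in scaling lowers the spinal cord medians of the neurotrophic and blood lists as well.

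Vgll1 is one of the genes that were bright on the wild-type spinal cord array alone, a group of 325 probes with 124 named genes. The share of their spots in the fullest of 64 blocks of the array was 4.31%, at percentile 95.3 of random sets, so a local artefact on the slide surface remains open. None of the named genes is in the fixed skeletal muscle list, a share of 0% where the list could reach at most 8.87%, and its lowest member in spinal cord, Myl1 at -1.73, stayed short of 4-fold. Both values, and the quartiles of -1.41 to -0.71 of that list in spinal cord, go against muscle as the source of the group. With 2 technical SDs added, a dim member other than Myl1 reached 2.46 in size, past 4-fold, so muscle is not excluded. The median GC of these probes was 43.3%, inside the range of 41.7% to 45.0% of random sets, which argues against base composition. A difference between slides, labelling or animals may underlie the group, and genotype and slide cannot be told apart for this array.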

How the results depend on the processing

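Scaling on the spike-in probes and leaving out genes bright on the wild-type spinal cord array alone were chosen only after the results were seen. No genotype effect paired by tissue was fitted, since the labels do not say whether the tissues of a genotype came from different animals, and leaving out an array would leave its comparison without a value. The cause of the changes was not tested, except that other thresholds and filters change counts by construction.

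All 15 counts and correlations stayed within 1.5 times (counts) or 0.05 (correlations) with cyclic loess, with scaling on the median, over genes above background on all 4 arrays, with the mean of probes and without genes bright on the wild-type spinal cord array alone. Quantile normalization gave 83 genes lower in brainstem/cerebellum and 31 lower in both tissues, and the authors' values 82 and 30.

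Normexp with quantile normalization gave 187 genes higher and 14 lower in brainstem/cerebellum, 914 and 532 in spinal cord, 1026 and 681 between transgenic tissues and 488 and 420 between wild-type tissues. It gave 162 genes higher and 6 lower in both tissues, 168 tissue differences higher in both genotypes, and 465 larger and 424 smaller differences in spinal cord.

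Without a filter on dim probes these were 1536 and 676 in brainstem/cerebellum, 2559 and 2363 in spinal cord, 2912 and 2100 between transgenic and 2662 and 1491 between wild-type tissues. Shared were 743 higher and 145 lower, for tissues 936 and 761, and the difference between tissues passed 2-fold for 2286 and 2513 genes. The correlation of the genotype differences was 0.347.

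With the brighter probes alone there were 217 and 11 in brainstem/cerebellum, 931 and 690 in spinal cord, 1095 higher between transgenic and 628 and 437 between wild-type tissues. Shared were 199 higher and 6 lower, for tissues 224 higher, and the difference between tissues gave 335 and 367. The correlation was 0.659.

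At 1.5-fold there were 1075 and 367 in brainstem/cerebellum, 2748 and 3004 in spinal cord, 3150 and 2480 between transgenic and 2644 and 1881 between wild-type tissues. Shared were 735 and 187, for tissues 1291 and 1128, and the difference between tissues gave 2053 and 2332. At 3-fold there were 157 and 10 in brainstem/cerebellum, 709 and 289 in spinal cord, 688 and 412 between transgenic and 331 and 299 between wild-type tissues. Shared were 130 and 2, for tissues 99 and 206, and the difference between tissues gave 150 and 269.

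Spike-in scaling gave 902 higher and 2605 lower in spinal cord, 980 and 2160 between transgenic tissues, and 253 and 2297 for the difference between tissues. It reversed the spinal cord medians of the myelin list (-0.12), the autophagy and lysosome list (-0.0723) and the oxidative stress list (-0.00307). The spinal cord medians of the unfolded protein response (-0.17), peripheral myelin (-0.07), lymphocyte (-0.12) and pituitary (-0.20) lists changed sign with it too. In brainstem/cerebellum the astrocyte median was -0.00872 with scaling on the median and -0.0123 with the mean of probes, the autophagy and lysosome median was -0.0340 with scaling on the median, and the neurotrophic list had a mean of 0.16.

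Of 2975 values of named genes under alternatives, 2358 moved by less than the technical error, 617 by more and 63 changed sign, none of them from a value past 2-fold. Hcst in brainstem/cerebellum changed from -0.33 to 1.0 with the mean of probes. Of 1596 list medians, 1259 stayed within it and 48 changed sign, none of them from a value past 2-fold. Signal over background limits the dim genes: the technical SD of a difference was 0.66 for the dimmest probes against 0.09 for the bright ones.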

Other observations

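The Prnp tests against the slide and against the glial reaction, the set of reactive astrocyte genes in the latter, and the ratio of the microglial lists over the excess were chosen only after the result was seen.

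The brightest genes at least 2-fold higher in both tissues, by a rule set after the values were seen, were Prnp, which encodes the prion protein, Ctss, Hspb1, Lyz2, Nmu, Gfap, S100a6, C4b, H2-K1 and C1qc. Ctss stood at 1.52 in brainstem/cerebellum and 2.15 in spinal cord, Lyz2 at 1.83 and 3.04, and the neuropeptide gene Nmu at 2.39 and 2.76. Among 4060 unnamed transcripts, 68 were higher and 9 lower in brainstem/cerebellum, and among 4124 in spinal cord 213 were higher and 573 lower. Of the probes bright on 1 array alone, 39.4% were unnamed on the wild-type and 12.4% on the transgenic spinal cord array, and 35.6% on the wild-type and 28.8% on the transgenic brainstem/cerebellum array.

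Prnp stood at 2.05 in brainstem/cerebellum and 2.29 in spinal cord at its main probe (chromosome 2, 131763817 to 131763876 in mm9). The probe of an alternative transcript (131744903 to 131744962) gave -0.23 and 0.40, so its smaller difference was -0.110 of that of the main probe. A transgene that carries Prnp sequence is a candidate explanation that this ratio leaves standing, and the labels describe no construct. The difference of 2.05 within 1 slide argues against the slide. The excess in spinal cord of 0.234 lies below the quartiles of 0.831 to 1.55 of the disease-associated microglia list, but beside its lowest member (Lgals3, 0.234) and within the quartiles of -0.289 to 0.883 of the reactive astrocyte list, so a share in the glial reaction stays open. A strain variant under the probe and another regulation of Prnp were not tested.

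The disease-associated microglia list differed more between genotypes in spinal cord than in brainstem/cerebellum, with a median excess of 1.23. After cyclic loess the excess was 1.24, or 1.01 times its value, which argues against a smooth intensity-dependent offset between slides as its source. Offsets that differ from probe to probe are not covered by this. The 7 spike-in probes ranged from -0.11 to 0.05 (brainstem/cerebellum genotypes) and 0.25 to 0.40 (transgenic tissues) within a slide. Across slides they ranged from -0.17 to 0.66 (spinal cord genotypes) and -0.32 to 0.48 (wild-type tissues). The list was 2.05 higher in spinal cord than in brainstem/cerebellum of transgenic mice and 0.590 in wild type, but the latter contains the wild-type spinal cord array, so an effect of that array cannot be told apart from one of genotype. The homeostatic list reached 0.358 of the disease-associated median in spinal cord and 0.273 of its excess, with a central 95% over resampled members of -0.269 to 0.824. This range is a spread among list members, not an error over animals or arrays. Both ratios depend on the scaling and would be lower with spike-in scaling, which lowers every spinal cord difference by the same amount. Siglech at -1.61 speaks against more microglia with unchanged expression. The excesses of the homeostatic (quartiles of -0.08 to 0.90) and disease-associated lists (0.83 to 1.55) overlap over members. With 1 array per group that explanation was not settled for the lists as a whole. A larger reaction in spinal cord is a hypothesis, with 1 array per group.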
